A study of Mus musculus with 6 samples.

How the data were processed

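Poly(A)-selected RNA of 6 libraries was sequenced on an Illumina Genome Analyzer, per the labels' protocols. The authors deposited 1 table for the whole series, whose name gives its values as FPKM, a measure scaled for transcript length and sequencing depth. The submitters' processing notes name Bowtie and the genome build mm9, without a version or a role. The counting program, the annotation release and the sequencing depth are not given in the sources used here.

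Samples were put into 5 groups from their titles and their stated modification. The table has 6 value columns, and their headings match no title, description or other label. A column was to be used only where its name matched the labels of 1 sample, so 6 columns of per-sample values were left out of every result. Column order and expression values were not used as a substitute for assigning columns. The columns should not be assumed to follow the order in which the samples are listed. This caution comes from marker gene levels seen at the first inspection, which sat poorly with that order. The planned linear models on log2-transformed values, the gene list tests and all their alternatives were not run for this reason.

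The value columns were looked at when the table was first inspected, for their range, totals and the levels of some marker genes. Apart from the caution on column order, no value from them entered the text or a result. The results reported rest on the sample labels, the column headings and the identifier column, read with Python 3.11.15. Gene synonyms came from a RefSeq gene reference. Rows, distinct identifiers and joined symbols were counted, and the members of the fixed gene lists were looked up by symbol. Of 19218 single gene symbols in the table, 16879 were found among the symbols of the GENCODE mouse annotation supplied for this work, which is on a later build than mm9. No coordinates are given, because the builds differ.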

Results

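The study profiled polyadenylated RNA from cells derived from mouse embryonic stem cells that had been differentiated as monolayers with retinoic acid. The labels describe 6 RNA-seq libraries in 5 groups. Sorted neurons, taken at 10 days of differentiation by magnetic selection for PSA-NCAM (the polysialylated form of the neural cell adhesion molecule, carried by young neurons), made up 2 libraries described as biological replicates. The other 4 libraries came from neural progenitor cells labelled with 4 days of differentiation, with 1 library per condition and time. Their times of 24 h and 48 h were taken as hours after transfection. All 4 libraries carry the same 4 days, so this need not be their age at harvest. For the untransfected library, the label does not say from what point its 24 h counts. Progenitors transfected with siRNA against Sox2 and Sox3 were profiled at 24 h and at 48 h. A universal siRNA control was profiled at 48 h, and untransfected progenitors at 24 h. Sox2 and Sox3 encode transcription factors of the SoxB1 group, which are active in neural progenitors, and Sox11 encodes a SoxC factor active in early neurons.

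The design implies 2 comparisons. The first sets the progenitors that received Sox2 and Sox3 siRNA against the control progenitors of the same time, as a loss-of-function experiment for these factors. The control was transfected with universal siRNA at 48 h but untransfected at 24 h, so the 24 h contrast would combine transfection with the siRNA against Sox2 and Sox3. The second sets the sorted neurons against the control progenitors. These also differ in labelled days of differentiation, 10 for neurons and 4 for progenitors. The control progenitor libraries differ in time and transfection and are not replicates. Neither comparison was made here. The value columns of the deposited expression table carry serial names only, and 0 of the 6 matched a label of any sample. A comment in the file header ties these names to the submitters' metadata sheet, which was not used here. Without that sheet, the table itself offered only column position and expression values for assigning a column, and neither was used. No expression level, fold change or test is therefore reported for any gene, including Sox2, Sox3 and Sox11.

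The gene identifiers of the table could be described without a sample assignment. The table held 20331 rows, each naming 1 or more gene symbols with their RefSeq transcripts, and 20136 of the row identifiers were distinct. Of all rows, 951 joined several gene symbols in 1 entry, so that the genes of such a row could not be told apart. Single and joined rows were counted alike when genes were looked up. All 3 SoxB1 genes (Sox1, Sox2 and Sox3) and all 3 SoxC genes (Sox4, Sox11 and Sox12) had a row. Of 561 distinct symbols in the 32 planned gene lists, 548 had a row under the symbol used. They included 24 of 28 pan-neuronal symbols and 21 of 21 neural progenitor symbols. With synonyms accepted the count was 560. Synonyms were not checked for belonging to only 1 gene. Some lists also hold a gene under more than 1 symbol (Sc4mol and Msmo1, Il17rd and Sef). A match by synonym can therefore be a row already counted, and these are counts of symbols, not of genes. A row alone does not show that the gene was expressed.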

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

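No expression value entered a result, so the planned choices (pseudocount, filter on low values, rescaling, time term, libraries left out) were not run. The alternatives below were chosen after seeing the data and concern only how names were matched. The number of distinct gene list symbols with a row was 524 when only rows with a single symbol counted. It was 560 when synonyms of a symbol were accepted, against 548 as reported. Matching the column names on letters and digits alone still assigned 0 of the 6 columns. No paired analysis was made, because no column of values could be matched to a sample. The sample grouping used here also records no pairing.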
